A study of Homo sapiens with 30 samples.

How the data were processed

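The series holds 30 libraries from THP-1 cells, an established human monocytic line, that were turned into macrophage-like cells with PMA and then given lipopolysaccharide (LPS), a bacterial cell wall component. PRO-seq, which reads RNA while polymerase is making it, 3′-seq, which reads mRNA ends and so gives mRNA level per polyadenylation site (PAS), and TED-seq, which measures poly(A) tail length, were each made at 0, 1, 2 and 4 h with 2 replicates, giving 24 libraries. A further 6 TED-seq libraries come from cells given actinomycin D, a transcription inhibitor, at 0, 1 and 2 h. Their titles give 15 min for the drug and do not tell whether it was present through the whole LPS time. Per the labels, PMA and, after 0 h, LPS were each used at 200 ng/mL, with 3 days of rest after PMA. Groups and replicate numbers were taken from the sample titles. In the 24 libraries without actinomycin D the treatment text contradicts most titles, so the titles, which match the replicate tables, were followed. The labels speak of biological replicates, but nothing states that they were separate cultures, so the p-values measure the spread between these samples only.

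Reads were aligned to hg38, with BWA for PRO-seq, STAR for 3′-seq and STAR 2.4.2a with BWA for TED-seq, per the labels. The 3′-seq peak table is in CPM, per the file headers, and keeps peaks whose CPM summed over all times was at least 5. The PRO-seq tables were deposited as CPM per transcript, as the values show, since each column is in whole multiples of 1 step and adds up to a fixed total. Overlapping transcripts share reads there, so a read can count more than once. Which part of a transcript was counted is not given in the sources used here. The tail tables give the mean tail length in nt per PAS isoform, scaled by the authors with RNA standards of known length, per the file headers. They carry no read counts, so the depth behind each tail is unknown. Their FDR columns are the authors' own Kolmogorov-Smirnov p-values between times within 1 replicate. The peak list's abundance column is a signal summed over times, per the file headers, and was not used in a test. The authors' combined table gives PRO-seq as log2 of the mean CPM plus 1, and pools replicates, so it was used only to check the joins. Whether duplicate reads were removed by molecular identifier is not given in the sources used here.

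Every value in the CPM tables was a whole multiple of the library's step (100% within a tolerance of 0.1), which gives the whole reads behind each value. The unit was nevertheless CPM, not counts as first planned, so the main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1). All changes are on that scale. Peaks took gene symbols from the tail tables, which paired 8435 of 47270 peaks with 6528 genes, and a gene's peaks were added up. Of 6529 symbols, 6496 were found in RefSeq. Assigning peaks to RefSeq genes by position gave the same name for 99.3% of the peaks named both ways. For PRO-seq, transcripts named in the tail tables were used, and where a gene had several the one with the highest mean was kept, for 6497 genes. CCL3 and CCL3L3 are near-identical copies, as are CCL4 and CCL4L2, so the split of reads within each pair is uncertain. For 3′-seq, genes with a mean CPM of at least 1 were tested. For PRO-seq the lowest 25% by mean were left out and the limma trend was on. Tails were tested in nt, PAS usage with diffSplice, and the difference between mRNA and nascent changes, or between tail changes with and without actinomycin D, as an interaction. Adjusted p-values are Benjamini-Hochberg over each comparison, with a threshold of 0.05, and each comparison with 0 h shares its 0 h libraries with the others. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 handled tables and plots.

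The main fit has no replicate block. Whether replicate numbers pair the samples was checked by correlating, across genes, the replicate differences at each pair of times. The correlations ran from 0.378 to 0.905 in 3′-seq, from 0.577 to 0.875 in PRO-seq and from 0.405 to 0.554 in TED-seq (6 pairs of times each), and the lowest of 3 was 0.0999 with actinomycin D. Replicates were therefore treated as paired in the first 3 assays, with blocked values printed beside many but not all of the unblocked ones, and not with actinomycin D. This decision has 2 weaknesses. Only 2 replicate numbers exist, so the rule of over 0.1 in every pair was read over pairs of times rather than pairs of replicates, and by the other reading the block would be only an alternative. The blocked counts had also been seen when the check was made. Calls that exist only with the block are for these reasons weaker evidence than calls made without it.

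The comparisons, the main tests, the 23 gene lists, the panel and the naming rule were fixed before the data were examined. Named genes are the 6 largest rises and 4 largest falls past the threshold whose groups do not overlap and whose mean lies above the median of those tested, up to 4 members of each list by adjusted p, a panel of 15 genes, the 6 PAS-usage genes with the smallest adjusted p, and the 5 highest and 5 lowest interactions. The following were chosen after seeing the data: the CPM filter for 3′-seq, applying the naming rule to blocked fits where the unblocked fit passed almost nothing, edgeR 4.0.16 on the recovered reads with TMM factors, TMM-scaled CPM, gene names by position, blocked and centred fits combined, and fits without 3′-seq 0 h replicate 1 or PRO-seq 0 h replicate 2. The alternatives fixed earlier were DESeq2 1.42.0, upper quartile factors, other pseudocounts (0.1 and 10) and filters, single peaks in place of genes, limma-voom on the recovered reads, a Simes test for PAS usage, the block, each library left out, only the 2 groups compared, stricter thresholds (1.5-fold, 10 nt), centred or log2 tails, other moderation, and Pearson correlation. On the log2 scale, 9 isoforms with a tail of 0 nt or less under actinomycin D were left out.

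The main fits, and the blocked limma and diffSplice fits given in the text with no TMM scaling or centring, were tested on simulated data with known changes at 2 h. The spread was that left in the real libraries after the replicate block was taken out. In 3′-seq, PRO-seq and PAS usage it was held at most at the median gene's. Runs without a simulated replicate effect therefore leave out replicate differences that the unblocked fits meet in the real libraries. For PRO-seq at 2 h (4872 genes) the unblocked fit recovered 61% of changes of 1 log2 unit and 98% of changes of 2. With a simulated replicate effect it recovered 0% and 70%, and the blocked fit 67% and 99%. For 3′-seq (6463 genes) the spread of all libraries let the unblocked fit recover 1% of changes of 2 log2 units, and 94% when the spread came from the libraries other than 0 h replicate 1. With a replicate effect as well as that spread the unblocked fit recovered 0% of changes of 1 and of 2 log2 units, and the blocked fit 32% and 94%. For tails (6202 isoforms) it recovered 1.49% of changes of 10 nt, 44.8% of 20 nt and 100% of 40 nt, and with a replicate effect 0%, 4.48% and 92.4%, and blocked 1.49%, 50.7% and 100%. With actinomycin D (7070 isoforms) and no replicate effect these were 20.9%, 97.0% and 100%, and for the interaction (4836 isoforms) 21% at 20 nt and 96% at 40 nt. A replicate effect was not simulated for tails with actinomycin D alone. The step comparing mRNA with nascent RNA (4829 genes) recovered 0% at 2 log2 units, and 86% without the spread of 0 h replicate 1. PAS usage (1494 genes) recovered 4% and 94% of changes of 3 log2 units in the same 2 settings.

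Further simulations, added after the results were seen, covered the blocked fits left out at first. With a replicate effect and the spread of the libraries kept, the blocked fit without 3′-seq 0 h replicate 1 recovered 79% of changes of 2 log2 units, and that without PRO-seq 0 h replicate 2 99%. For mRNA beyond nascent RNA the blocked fit without 3′-seq 0 h replicate 1 recovered 57%, and without both libraries 55%. The blocked interaction recovered 31% at 20 nt and 100% at 40 nt, where the unblocked one recovered 2% and 71%. Blocked PAS usage recovered 5% of changes of 3 log2 units with the spread of all libraries and 91% without 0 h replicate 1. With the spread of all libraries the blocked fits without 3′-seq 0 h replicate 1 recovered 0% of changes of 2 log2 units, both for mRNA and for mRNA beyond nascent RNA. With the whole spread, not held at the median gene's, and a replicate effect, PRO-seq recovered 0% and 53% of changes of 1 and 2 log2 units unblocked and 26% and 93% blocked. The blocked fit of 3′-seq without 0 h replicate 1 then recovered 71%, with a false share of 8.54%.

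At the 0.05 threshold the false share among calls was higher than 5% in several fits: 9.66% for PRO-seq unblocked and 9.60 to 9.78% blocked, 8.49% for tails unblocked and 9.52% blocked, and 7.05% with actinomycin D. For DESeq2 on 3′-seq with the spread of all libraries it was 66% without and 57.1% with a simulated replicate effect, so its counts there are not to be relied on. In 3′-seq with the spread of the other libraries it was 0.741% for limma unblocked, and 1.42 to 2.33% blocked. Over the settings simulated it ran up to 16.4% for PRO-seq blocked without 0 h replicate 2 and 15.2% for mRNA beyond nascent RNA blocked without 3′-seq 0 h replicate 1, so calls of these fits hold more false ones than the threshold says.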

Results

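The time course asks how nascent RNA, mRNA level and poly(A) tail length move in THP-1 macrophage-like cells over 4 h of LPS, with 2 libraries per assay and time. The 3′-seq libraries held 2081582 and 5572570 reads in the listed peaks at 0 h, 1323830 and 7290956 at 1 h, 21828164 and 6831540 at 2 h, and 19367065 and 8429731 at 4 h (replicates 1 and 2). For PRO-seq the counts summed over transcripts, where a read in overlapping transcripts counts more than once, were 9372549 and 3363601, 10522869 and 26381291, 15870377 and 32494655, and 13856670 and 26701809. Tail lengths were given for 6202 isoforms without and 7070 with actinomycin D. Median tails without it were 110 and 106 nt at 0 h, 108 and 102 at 1 h, 107 and 96.7 at 2 h, and 101 and 102 at 4 h. In each pair of values, replicate 1 comes first. The 3′-seq library of 0 h replicate 1 put 47.4% of its CPM in 10 peaks, against 3.88 to 6.48% in the other 7. Peaks paired with a gene, on which the gene tests rest, held 8.36% of its CPM, against 45.5 to 55.6% in the other 7. The PRO-seq library of 0 h replicate 2 held the 10 tested chemokine genes, a list fixed beforehand, at a median of 15.1% of their 1 h level, against 1.57% in replicate 1. Both enter every comparison with 0 h.

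Nascent RNA of inflammatory genes was higher after 1 h of LPS. TNF, the cytokine tumour necrosis factor, went from 11.7 and 33.0 CPM to 436 and 257, a log2 change of +4.01 ± 0.69 (SE with the replicate block, n = 2; adjusted p = 0.0974 without the block and 0.00525 with it). TNFAIP3, which encodes the NF-kB inhibitor A20, went from 30.4 and 101 to 947 and 550 CPM (+3.67), and the chemokine gene CCL4 from 0.427 and 5.95 to 155 and 39.7 (+4.66). In the other direction, TREM2, a macrophage surface receptor gene, went from 11.8 and 9.51 to 0.380 and 0.455 CPM (-3.04 ± 0.28, adjusted p = 0.0814 without the block and 0.00270 with it), and the lysosomal protease gene CTSD from 20.3 and 40.4 to 1.33 and 2.50 (-3.38). Without the block, limma passed 0 of 4872 genes at 1 h, with 995 at an unadjusted p under 0.05. edgeR also called 0, and DESeq2 335. With the replicate block 359 genes rose and 1242 fell. The median gene moved by -0.39, and relative to it TNF changed by +4.40 and TREM2 by -2.65. TMM scaling, under which the median moved by 0.06, turned the blocked split into 707 higher and 542 lower. Without 0 h replicate 2 the blocked fit gave 388 and 1641.

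Gene lists fixed beforehand were counted at 1 h. Adjusted over the list alone and without the block, nascent RNA was higher for 10 of 10 chemokine genes, 16 of 26 reported targets of ZFP36 (an mRNA-decay protein), 13 of 18 NF-kB pathway genes, 4 of 9 cytokines, 5 of 24 immediate-early genes and 5 of 14 tissue remodelling genes, while 5 of 14 macrophage identity genes were lower. Most of the ZFP36 targets, such as TNF, CCL20 and NFKBIA, also stand in the chemokine, cytokine, NF-kB, immediate-early or remodelling lists. Counts of these lists are therefore not separate evidence. With the block and over all genes, 10 chemokine genes, 20 ZFP36 targets (1 lower), 14 NF-kB genes, 7 cytokines (1 lower), 12 immediate-early genes (1 lower) and 7 remodelling genes (1 lower) rose. Among macrophage identity genes 1 rose and 8 fell, CSF1R by -2.38 and ITGAM by -2.76. The other lists are to be read beside all genes, of which 359 rose and 1242 fell with the block and 707 and 542 after TMM scaling. Their counts with the block were: interferon-stimulated 3 of 13 higher and 1 lower, poly(A) tail machinery 3 of 17 higher, ARE-binding regulators 2 of 14 higher and 1 lower, lysosome 2 of 28 higher and 8 lower, glycolysis 2 of 14 higher and 8 lower, cholesterol synthesis 2 of 18 higher and 6 lower, unfolded protein response 1 of 16 higher and 2 lower, nuclear oxidative phosphorylation 0 of 23 higher and 6 lower, and cell cycle 0 of 15 higher and 6 lower, AURKA by -1.80. Of 58 ribosomal protein genes and 3 histone genes 0 passed in limma, 1 of 5 C2H2 repressors (ZNF267) rose, as did the 1 promyelocyte granule gene (SRGN, +3.22), the 1 epithelial or fibroblast gene (PDGFRA) gave -0.17, and no lymphoid or mitochondrially encoded gene was measured. Without the block camera called 30 of 76 PRO-seq list tests at the preset correlation and 0 with an estimated one, where chemokines had adjusted p = 0.119 with an estimated correlation.

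At 2 h OAS1, an antiviral enzyme gene, stood at 28.4 and 17.8 CPM against 3.63 and 1.78 at 0 h (+2.71 ± 0.21 with the block, n = 2; adjusted p = 0.109 without it and 8.8e-04 with it). With the block and over all genes 12 of 13 interferon-stimulated genes rose, with camera adjusted p = 0.144 with an estimated correlation and 0.0862 with the block as well. No test of 2 h against 1 h was made. MERTK, which encodes a receptor for dying cells, went from 56.9 and 60.7 to 0.819 and 3.23 CPM (-4.43 ± 0.42, adjusted p = 0.00146 with the block), and the adhesion gene PECAM1 from 51.1 and 54.7 to 1.26 and 5.94 (-3.77). Without the block limma passed 0 genes at 2 h (775 at an unadjusted p under 0.05; edgeR 0, DESeq2 314), and with it 392 rose and 756 fell, 591 and 421 after TMM scaling and 454 and 1211 without 0 h replicate 2. The median gene moved by -0.24.

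At 4 h OAS2, another antiviral enzyme gene, stood at 192 and 67.3 CPM against 7.58 and 7.14 at 0 h (+3.78 ± 0.32 with the block, n = 2; adjusted p = 0.0906 without it and 0.00100 with it). TNF was still at 314 and 65.3 CPM (+2.80, adjusted p = 0.0315 with the block, and +4.20 without 0 h replicate 2 as well). CCL20, a chemokine gene, gave +1.11 and adjusted p = 0.152 with the block, but +1.97 and adjusted p = 0.0186 without 0 h replicate 2 as well. PLXDC2, a plexin-domain gene, fell with the block from 90.4 and 157 to 3.68 and 16.3 CPM (-3.74). Without the block limma passed 0 genes (560 at an unadjusted p under 0.05; edgeR 0, DESeq2 192). With it 319 rose and 390 fell, 357 and 300 after TMM scaling and 405 and 735 without 0 h replicate 2. The median gene moved by -0.14. All 13 of the 13 interferon-stimulated genes rose with the block, but with an estimated correlation camera called 0 of the 76 PRO-seq list tests.

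**Figure D1:**
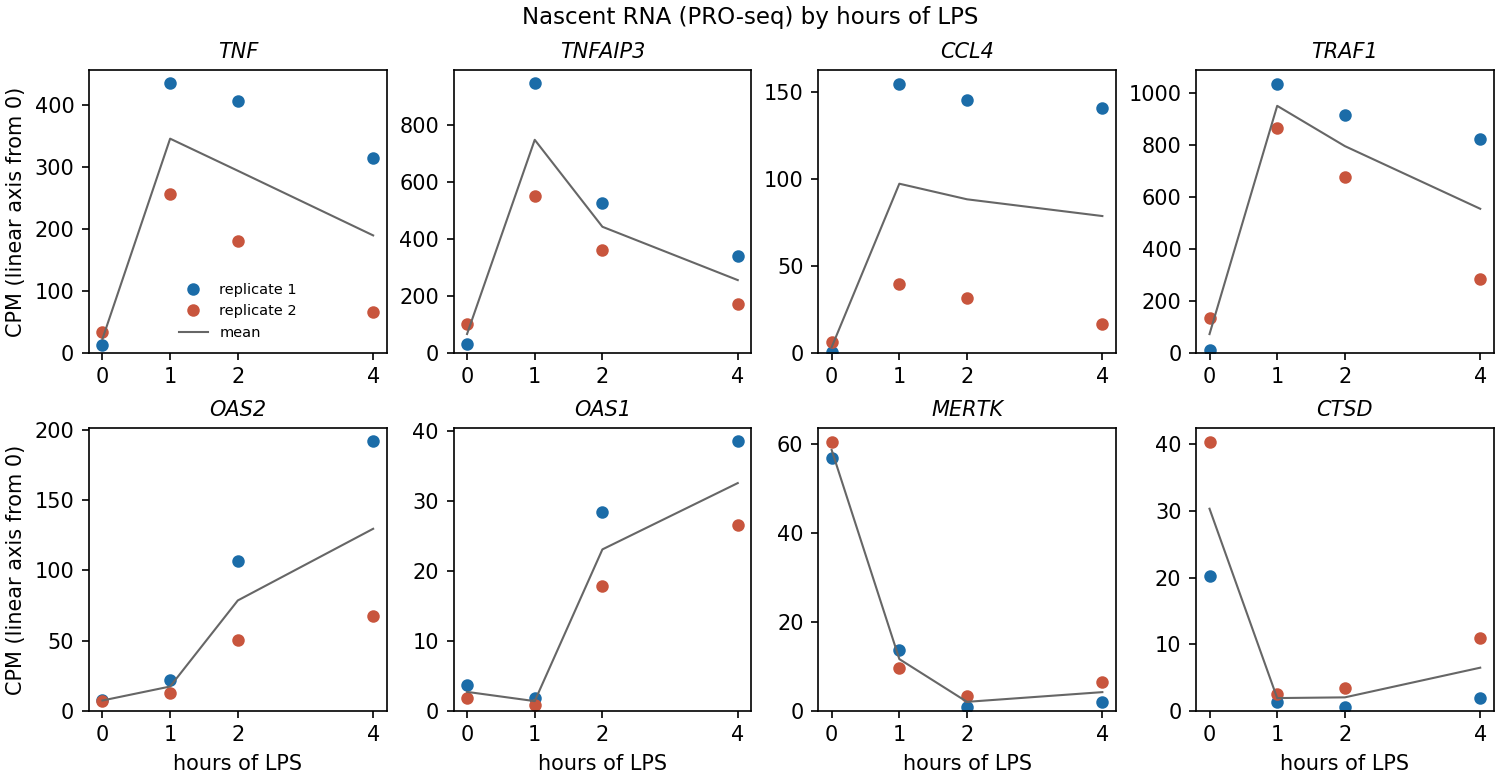
Nascent RNA (PRO-seq CPM) against hours of LPS for 8 genes, with a point per replicate and a line through the means. TNF, TNFAIP3, CCL4 and TRAF1 are high from 1 h, OAS2 and OAS1 from 2 to 4 h, and MERTK and CTSD are lower at each later time than at 0 h.

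Between 1 h and 4 h interferon-induced genes rose, and here genes passed without the block. SP110, an interferon-induced nuclear body gene, went from 1.24 and 2.05 to 49.8 and 47.9 CPM (+4.26 ± 0.31, n = 2, adjusted p = 0.0119) and OAS3 from 4.94 and 7.66 to 175 and 103 (+4.23 ± 0.40, adjusted p = 0.0119). APOBEC3G, a cytidine deaminase gene, gave +3.50 and UBE2L6, which encodes an ISG15-conjugating enzyme, +3.75. In all 16 genes rose and 0 fell, with 547 at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 163. Leaving out either 1 h or either 4 h library left 0 calls. The change itself does not use the 0 h levels, but the 0 h libraries enter the spread behind the SE, and with only the 2 groups compared 0 genes passed. With the block 502 rose and 152 fell, 240 and 272 after TMM scaling and 849 and 249 without 0 h replicate 2. The median gene moved by +0.25, and relative to it SP110 changed by +4.00. Interferon-stimulated genes were higher in 4 of 13 over all genes and in 10 adjusted over the list alone (camera adjusted p = 0.249 with an estimated correlation). GEM, a small GTPase gene, fell with the block from 546 and 294 to 46.0 and 65.0 CPM (-2.85), and PLXDC2 by -3.28, while TNF gave -1.21, with adjusted p = 0.266 with the block and 0.0479 without 0 h replicate 2 as well.

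At the mRNA level ABTB2, a gene for an ankyrin and BTB domain protein, went from 0.726 and 0 CPM at 0 h to 130 and 94.2 at 4 h (+6.41 ± 1.36, n = 2, adjusted p = 0.0144), and TRAF1, an NF-kB-induced adaptor gene, from 2.90 and 1.86 to 329 and 191 (+6.24 ± 1.36, adjusted p = 0.0144). These 2 were the calls without the block among 6463 genes at 4 h, with 425 at an unadjusted p under 0.05, and edgeR called 0 and DESeq2 281. Any single 3′-seq library left out gave 0, except 0 h replicate 2, without which 3670 genes passed. With the block 41 rose and 2 fell. Among them BCL2A1, a survival gene, went from 36.3 and 12.3 to 1144 and 929 CPM (+5.53, adjusted p = 0.00198), CCL20 to 2282 and 535 (+5.47) and CXCL8, which encodes interleukin 8, from 498 and 26.3 to 5597 and 3633 (+5.27). PUF60, a splicing factor gene, fell from 111 and 84.5 to 0.498 and 19.3 CPM (-4.15) and CCDC85B from 74.4 and 164 to 0.422 and 21.6 (-4.30). TNF stood at 1725 and 537 against 117 and 111 (+3.07, adjusted p = 0.212 with the block, and +2.90 with adjusted p = 0.0139 without 0 h replicate 1 as well). The median gene moved by +1.14, and by -0.39 without 0 h replicate 1, so values are read against it: ABTB2 +5.27, ACTB -1.71 and GAPDH -1.28. TMM scaling with the block left 0 calls. The blocked fit without 0 h replicate 1 gave 405 higher and 1250 lower.

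At 1 h and 2 h the unblocked fit passed 0 mRNAs. CCL20 mRNA stood at 1080 and 190 CPM at 1 h against 81.6 and 6.50 at 0 h (+4.19, adjusted p = 0.586), and TNF at 718 and 1378 (+3.12). At 2 h TRAF1 stood at 171 and 188 CPM (+5.75, adjusted p = 0.148 without the block and 0.00293 with it) and TNFAIP3 at 97.5 and 465 against 2.90 and 18.4 (+4.62, adjusted p = 0.0276 with it). TMM scaling with the block left 0 calls at 2 h, with adjusted p = 0.238 for TRAF1 and 0.357 for TNFAIP3. limma gave 143 and 266 genes at an unadjusted p under 0.05 at 1 h and 2 h, edgeR called 0 at both and DESeq2 23 and 55. With the block 0 and 25 rose, and without 0 h replicate 1 as well 30 rose and 3 fell at 1 h and 136 rose and 35 fell at 2 h. Without 0 h replicate 2 the unblocked counts were 4114 and 4190. The median gene moved by +1.40 and +1.41. From 1 h to 4 h 0 mRNAs passed with or without the block (31 and 88 at an unadjusted p under 0.05; edgeR 0, DESeq2 15), and the median moved by -0.23. The blocked fit without 0 h replicate 1 called 753 there, TRAF1 among them, which went from 6.22 and 28.6 to 329 and 191 CPM (+4.11).

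**Figure D2:**
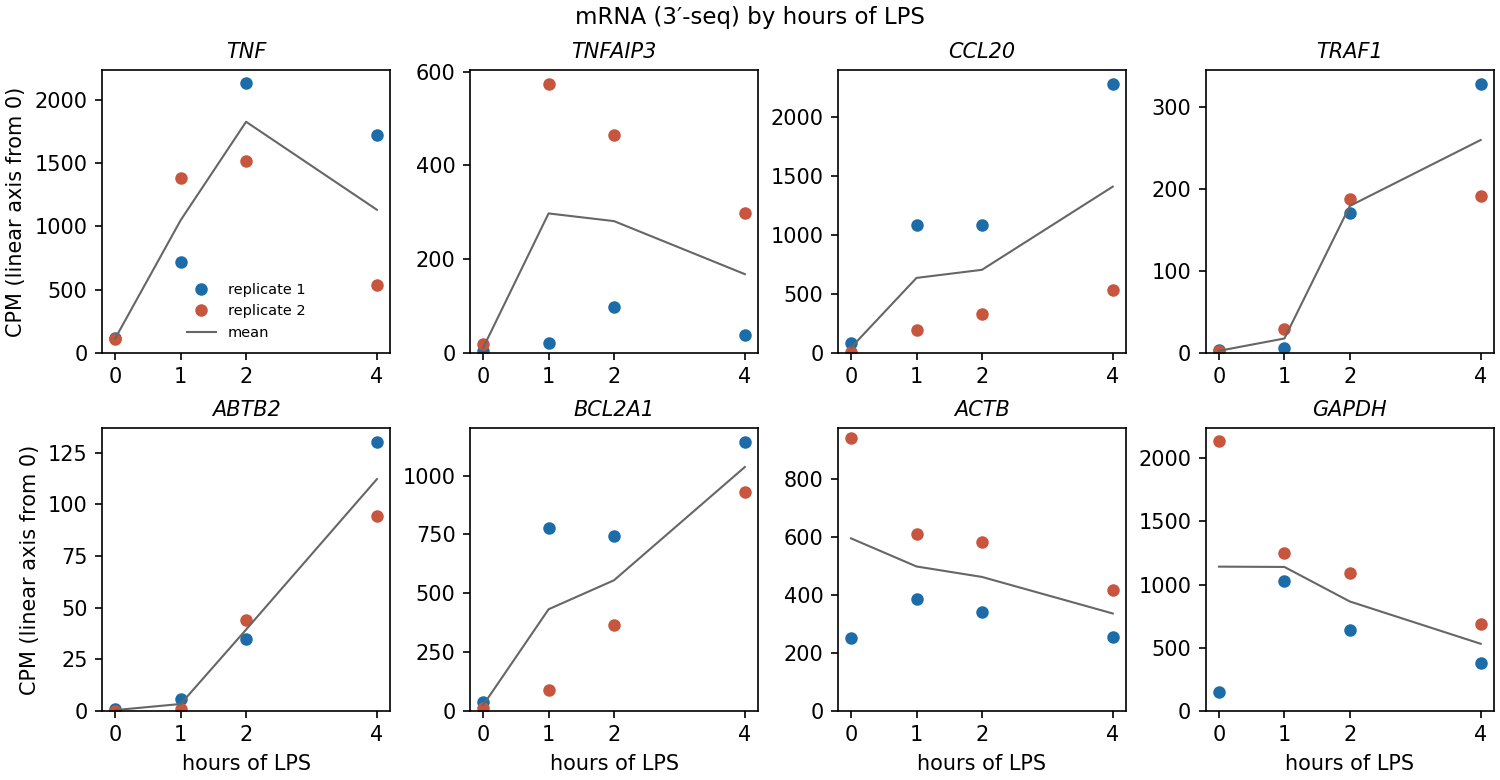
mRNA level (3′-seq CPM) against hours of LPS for 8 genes, with a point per replicate and a line through the means. TRAF1 and ABTB2 rise from under 3 CPM at 0 h to over 94 CPM in both replicates at 4 h, while GAPDH and ACTB differ between the 0 h replicates.

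Adjusted over the list alone and without the block, mRNA was higher at 4 h for 13 of 15 chemokines, 15 of 27 ZFP36 targets, 9 of 18 NF-kB genes (1 over all genes), 5 of 9 cytokines, 7 of 21 remodelling genes, 1 of 15 ARE-binding regulators, 1 of 2 promyelocyte granule genes and the 1 epithelial or fibroblast gene, PDGFRA (the only member measured, so its p is in effect unadjusted). At 1 h these were 6 chemokines, 12 ZFP36 targets and 3 of 25 immediate-early genes, and at 2 h 12 chemokines, 18 ZFP36 targets, 10 immediate-early genes, 8 NF-kB genes, 4 cytokines and 5 remodelling genes. In limma 0 members passed at 4 h among 13 interferon-stimulated, 15 poly(A) machinery, 65 ribosomal protein, 41 oxidative phosphorylation, 30 lysosome, 19 cholesterol synthesis, 17 glycolysis, 20 unfolded protein response, 20 macrophage identity, 5 C2H2 repressor, 18 cell cycle, 2 lymphoid (TRAC and GNLY) and 4 histone genes, and no mitochondrially encoded gene was measured. Relative to the median gene, chemokines changed by +3.61 at 4 h (adjusted p = 0.0293 with an estimated correlation) and ZFP36 targets by +2.18 (adjusted p = 0.0137 with an estimated correlation). These lists share members, CCL20 among them, so their results are not independent. Of 76 list tests camera called 38, and 5 with an estimated correlation: chemokines and ZFP36 targets at 2 h and 4 h, and ZFP36 targets at 1 h. With the block these 5 became 0, at adjusted p = 0.0843 for both lists at 2 h, 0.119 for both at 4 h and 0.323 for ZFP36 targets at 1 h with an estimated correlation. Without 0 h replicate 1 and with the block, 1 sample was left at 0 h and the median gene moved by -0.39 at 4 h. No list result is therefore read from that fit.

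Whether mRNA moved beyond nascent RNA was tested per gene in 4829 genes. CCL20 at 4 h gave +5.47 in mRNA and +1.11 in nascent RNA, a difference of +4.37 ± 1.62 (n = 2 per assay and time, adjusted p = 0.559), and TNF gave +3.07 and +2.80. limma passed 0 genes at 1, 2 and 4 h, with 532, 397 and 252 at an unadjusted p under 0.05, and 0 with the block. The median difference was +1.76, +1.67 and +1.46, and +0.28, +0.19 and -0.08 without 0 h replicate 1 of 3′-seq. The blocked fit without that library called 11 higher and 1 lower at 1 h, 58 and 8 at 2 h and 82 and 176 at 4 h. There BCL2A1 had a difference of +5.21 (adjusted p = 0.00881) and CCL20 of +5.04 (adjusted p = 0.00870) at 4 h, RPL35, a ribosomal protein gene, had -4.79, and MERTK at 2 h had +4.05, with mRNA at -0.38 in that fit (+1.22 with all libraries) and nascent RNA at -4.43. TMM scaling of the same fit gave 1 higher and 5 lower at 1 h, 32 and 48 at 2 h and 77 and 417 at 4 h, so the balance at 1 h and 2 h depends on the scaling. That fit keeps 0 h replicate 2 of PRO-seq, without which the nascent change of CCL20 was +1.97. Leaving out both libraries gave 208 higher and 55 lower at 1 h, 131 and 23 at 2 h and 84 and 110 at 4 h, with CCL20 at +4.18 (adjusted p = 0.0130), BCL2A1 at +5.34, RPL35 at -4.14 and TNF at -1.30 (adjusted p = 0.419) at 4 h, and MERTK at +4.35 at 2 h. Without 0 h replicate 2 of 3′-seq instead, the unblocked counts were 3434, 3363 and 3050.

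PAS usage, here the division of 3′-seq reads among the named sites of a gene, was tested in 1494 genes with 2 or more such sites. Only 8435 of 47270 peaks were named, so a gene's other sites did not enter the test. At the VEGFA site at position 43786483 of chromosome 6 (hg38, plus strand) the share was 2.86% and 80% at 0 h and 100% and 85.7% at 1 h (adjusted p = 0.999). diffSplice passed 0 genes at 1, 2 and 4 h, with 12, 6 and 10 at an unadjusted p under 0.05, and the Simes test 0. With the block these were 0 (25, 18 and 29). DENND3, APH1A, TM4SF19 and ABCC3 followed at 4 h, each at adjusted p = 0.999 or above. Without 0 h replicate 2, which leaves 0 h replicate 1 as the lone sample at 0 h, 50, 42 and 44 genes passed, and without 0 h replicate 1 0 did.

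Poly(A) tails of a few isoforms were much shorter after LPS. The isoform of CYC1, which encodes cytochrome c1 of the respiratory chain, went from 156 and 163 nt at 0 h to 70.1 and 68.5 at 1 h (-90.5 ± 4.77 SE, n = 2, adjusted p = 8.4e-04), 65.1 and 68.3 at 2 h and 62.0 and 65.1 at 4 h. STXBP2, a secretion gene, went from 169 and 192 to 78.7 and 79.7 nt at 1 h (adjusted p = 0.0124), and the read-through transcript BCL2L2-PABPN1 from 143 and 142 to 77.3 and 75.3 (-66.1, adjusted p = 0.00373). These 3 were the calls at each of 1, 2 and 4 h, with 57, 335 and 774 isoforms at an unadjusted p under 0.05. The typical isoform moved by -3.54, -5.94 and -6.28 nt. The counts moved when a library was left out: without 0 h replicate 1 to 9, 8 and 9, without 0 h replicate 2 to 5 at each time, without 1 h replicate 2 to 10 at 1 h, without 2 h replicate 1 to 8 at 2 h and without 4 h replicate 2 to 5 at 4 h.

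CCRL2, an atypical chemokine receptor gene, had tails of 83.7 and 71.7 nt at 0 h, 134 and 123 at 1 h, 80.3 and 76.2 at 2 h and 58.1 and 50.8 at 4 h. It was the 1 call between 4 h and 1 h (-74.1 ± 6.27, adjusted p = 0.0260; 379 isoforms at an unadjusted p under 0.05), lost without either 2 h library and joined by 1 more without 1 h replicate 1 or either 4 h library and by others, to 8, without 1 h replicate 2. At 1 h CCRL2 passed only with the block (+50.7, adjusted p = 0.0913 without it and 0.00138 with it). With the block NLRP3, an inflammasome gene, also fell between 1 h and 4 h (-41.0 nt, adjusted p = 0.0148), and MYBPH, chosen after its values were seen, at 4 h (-32.9, adjusted p = 0.0355). TNF tails were 118 and 109 nt at 0 h, 134 and 138 at 1 h, 107 and 104 at 2 h and 96.7 and 105 at 4 h (+22.1 ± 5.46 at 1 h, adjusted p = 0.998). ACTB stood at 95.3 and 89.3 nt at 0 h and 91.0 and 82.5 at 4 h. Relative to the median isoform, chemokine tails changed by +7.31 nt at 1 h and +17.1 at 2 h, and interferon-stimulated tails by +10.1 at 4 h. Macrophage identity at 4 h gave -7.99. No chemokine or interferon-stimulated isoform passed the threshold at these times without the block. camera called 20 of 76 tail list tests, and 0 with an estimated correlation, where chemokines at 2 h had adjusted p = 0.485 with an estimated correlation.

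**Figure D3:**
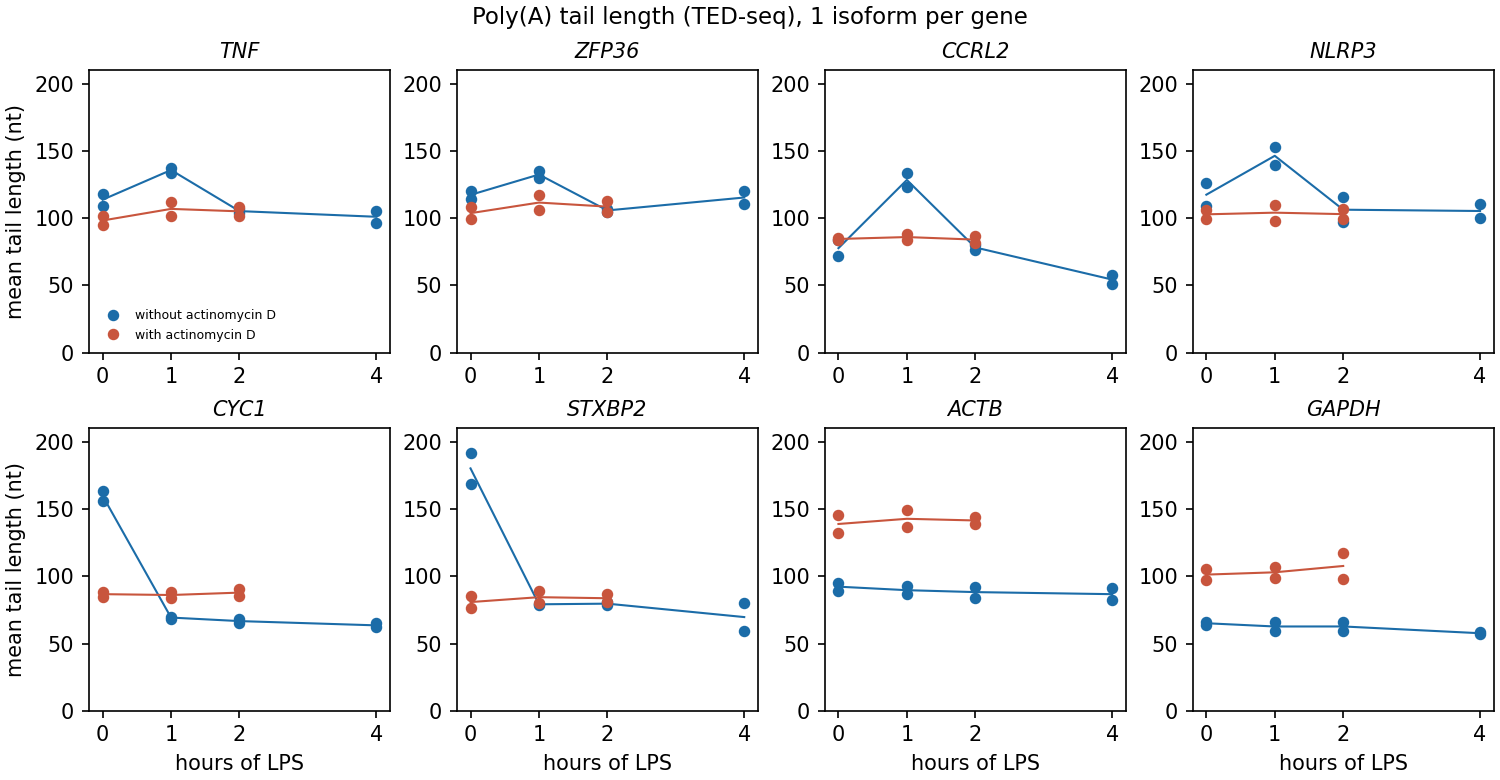
Mean poly(A) tail length (nt) against hours of LPS for isoforms of 8 genes, without (blue) and with (red) actinomycin D, with a point per replicate and a line through the means. CYC1 and STXBP2 start at 156 to 192 nt without the drug and lie under 90 nt afterwards, and with the drug they are under 91 nt at each time.

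With actinomycin D, tails of CDK5RAP3, which encodes a kinase regulator, went from 125 and 133 nt at 0 h to 237 and 237 at 2 h (+108 ± 6.03, n = 2, adjusted p = 2.1e-09), and those of PABPC1, the cytoplasmic poly(A)-binding protein, from 80.6 and 97.7 to 128 and 144 (+46.7 ± 6.65, adjusted p = 0.00415). HNRNPU, an RNA-binding protein gene, gave +63.2, the non-coding RP11-745O10.4 +45.4, YTHDF2, which encodes a reader of methylated mRNA, +35.3 and NAP1L1, a histone chaperone gene, +32.4. The HNRNPU site lies 181 nt from a neighbour, and in pairs of sites 150 to 200 nt apart the median difference in tail was 149 nt. These 6 were the calls among 7070 isoforms at 2 h (92 at an unadjusted p under 0.05). At 1 h limma passed 0 (38). Subtracting library medians left 1 call at 2 h. Leaving out any single library raised the counts, to 16 without 0 h replicate 1, 18 without 0 h replicate 2, 24 without 1 h replicate 1, 29 without 1 h replicate 2, and 19 without either 2 h library at 1 h, and to 27, 30, 47, 47, 42 and 45 at 2 h for 0 h, 1 h and 2 h replicates 1 and 2. TNF tails were 95.1 and 102 nt at 0 h and 102 and 108 at 2 h, and PABPC1 was the 1 of 13 poly(A) machinery members to pass. camera called 0 of 36 list tests.

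The LPS effect on tails differed between the libraries with and without actinomycin D for 2 of 4836 isoforms at both 1 h and 2 h. CYC1 tails shortened without the drug, and with it they stood at 84.8 and 88.7 nt at 0 h and 84.2 and 88.0 at 1 h. The change with the drug minus the change without it was +89.9 ± 6.29 nt at 1 h (n = 2 per group, adjusted p = 4.3e-05) and +94.3 at 2 h (adjusted p = 2.5e-05). STXBP2 stood at 76.3 and 85.4 nt at 0 h and 80.0 and 89.0 at 1 h with the drug, and the same difference was +105 ± 11.2 (adjusted p = 0.00211) and +103 at 2 h (adjusted p = 0.00240). In both genes the 0 h tails without the drug were the long ones. The libraries with the drug are a set of their own, with no drug-free library in it. An effect of the drug can therefore not be told apart from another difference between the 2 sets. Counts at an unadjusted p under 0.05 were 26 and 140. Leaving out a library moved the counts at 1 h to 11 (0 h replicate 1), 5 (0 h replicate 2) and 8 (1 h replicate 2) without the drug, and to 4, 6 and 6 with the drug for 0 h replicate 1, 0 h replicate 2 and 1 h replicate 1. At 2 h they moved to 10 (0 h replicate 1), 5 (0 h replicate 2) and 4 (2 h replicate 2) without the drug and to 4, 7 and 4 for 0 h replicate 1, 0 h replicate 2 and 2 h replicate 2 with it.

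Across genes, tail change went weakly with mRNA change, with a Spearman correlation of 0.146 at 1 h, 0.226 at 2 h and 0.314 at 4 h, and with nascent RNA change, at 0.164, 0.360 and 0.272. Genes are not independent replicates, so no p is given. TNF, at 1 h, had +22.1 nt with +3.12 in mRNA and +4.01 in nascent RNA, and CYC1 had -90.5 nt.

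**Figure D4:**
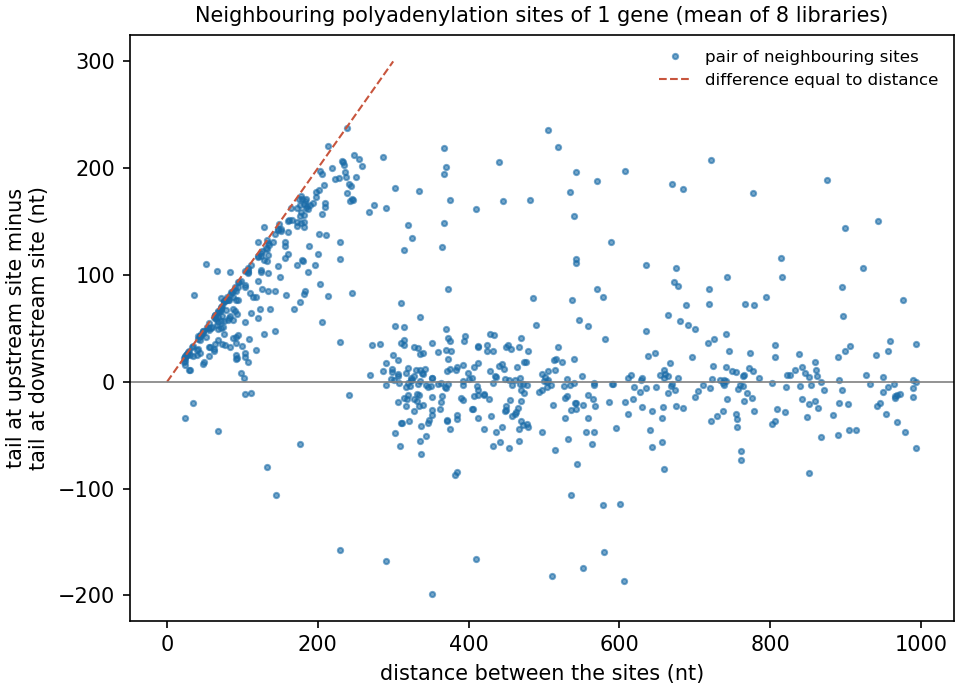
Upstream minus downstream tail length (nt) against the distance (nt) between neighbouring sites of 1 gene, for pairs up to 1000 nt apart, as the mean of the 8 libraries without actinomycin D. The dashed line marks a difference equal to the distance; the slope in the 225 pairs within 200 nt was 0.733, and 71.1% of pairs 20 to 50 nt apart but 12.8% of those 150 to 200 nt apart lay within 10 nt of that line.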

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

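The tests of these differences were fixed in advance, and the remark on neighbouring sites was added after the result was seen. Isoforms of STXBP2 and CYC1 stood out because their LPS response differed between the libraries with and without actinomycin D, by a test of the difference itself. The drug and the set of libraries cannot be told apart here. STXBP2, a regulator of granule release, went from 169 and 192 nt to 78.7 and 79.7 at 1 h without the drug and from 76.3 and 85.4 to 80.0 and 89.0 with it. Its change with the drug minus that without was 105 nt at 1 h and 103 nt at 2 h. CYC1, a mitochondrial electron carrier gene, went from 156 and 163 nt to 70.1 and 68.5 without the drug and from 84.8 and 88.7 to 84.2 and 88.0 with it, and the same difference was 89.9 and 94.3 nt. Neither gene has a neighbouring site in the tail tables without the drug. Neighbours among sites measured with the drug, or among 3′-seq peaks without a name, were not looked for.

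PRO-seq changes differed between 4 h and 1 h for 16 genes, SP110 and OAS3 among them, by a test of 4 h against 1 h. For CCRL2 the tail change at 4 h differed from that at 1 h by -74.1 nt.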

How the results depend on the processing

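Each count in the text was made again under other choices, and those that moved by more than 1.5 times are given here, with some of the calls that changed. The first set was chosen in advance, and fits joining the replicate block with another change, edgeR, TMM-scaled CPM and names by position were chosen after the results were seen. The cause was not tested for any of these moves. No correlation changed sign. The balance of blocked calls did turn: in PRO-seq at 1 h from 359 higher and 1242 lower to 707 and 542 after TMM scaling, at 2 h from 392 and 756 to 591 and 421, at 4 h from 319 and 390 to 357 and 300, and between 1 h and 4 h from 502 and 152 to 240 and 272. For mRNA beyond nascent RNA without 0 h replicate 1 of 3′-seq it turned under TMM scaling from 11 and 1 to 1 and 5 at 1 h and from 58 and 8 to 32 and 48 at 2 h, and in 3′-seq at 4 h from 41 and 2 to 405 and 1250 without 0 h replicate 1. The values of 6 measurements of named genes also changed sign, none of which had passed its test without the block. Over all choices, 94 of 1447 repeated values of named genes lost a call and 145 gained one, and not all of these are listed. Leaving out 1 library leaves a group with 1 sample, which is then assumed to vary like the other groups. A read minimum for tails was not run, since the tail tables give no read counts, nor were other PRO-seq regions, since the tables do not separate them. Limiting the correlations to genes called in the unblocked mRNA fit gave no value, since it called 0, 0 and 2.

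For 3′-seq the replicate block gave 25 calls at 2 h and 43 at 4 h, and 33, 171, 1655 and 753 (1, 2 and 4 h against 0 h, and 4 h against 1 h) when 0 h replicate 1 was also left out. DESeq2 gave 23, 55, 281 and 15. On TMM-scaled CPM the block left 0 at 2 h and at 4 h. The 2 calls at 4 h, ABTB2 and TRAF1, became 0 with edgeR and TMM, upper quartile factors, TMM-scaled CPM with or without the block, a pseudocount of 10, only the 2 groups compared, single peaks or names by position, and 1 with a pseudocount of 0.1. edgeR with TMM and the block gave 420. Leaving out each library in turn gave from 0 to 4114 at 1 h, 0 to 4190 at 2 h and 0 to 3670 at 4 h.

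For PRO-seq the replicate block gave 1601, 1148, 709 and 654 calls, 1249, 1012, 657 and 512 after TMM scaling, 2029, 1665, 1140 and 1098 without 0 h replicate 2, and 1375, 1113, 669 and 567 in edgeR. DESeq2 gave 335, 314, 192 and 163. A pseudocount of 10 gave 3 at 2 h and 5 at 4 h. The 16 calls between 4 h and 1 h, SP110 and OAS3 among them, became 0 in edgeR with TMM or upper quartile factors and with only the 2 groups compared, and 0 to 15 with a library left out.

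For tails without actinomycin D the replicate block gave 2 calls between 4 h and 1 h, CCRL2 and NLRP3, and with library medians subtracted 5 at 1 h and 2 between 4 h and 1 h. With only the 2 groups compared, 1 remained at 1 h and 0 between 4 h and 1 h. A library left out gave from 2 to 10 at 1 h, 2 to 8 at 2 h, 3 to 9 at 4 h and 0 to 8 between 4 h and 1 h. With actinomycin D at 2 h the replicate block gave 31 (26 higher and 5 lower), medians subtracted 1 and with the block 2, the log2 scale 2, moderation with trend and robust 15, and only the 2 groups 47, with 19 at 1 h. A library left out gave 16 to 29 at 1 h and 27 to 47 at 2 h. The difference between the experiments gave 1 at 2 h on the log2 scale, and 2 to 11 at 1 h and 2 to 10 at 2 h with a library left out. With the block the change with the drug minus that without also passed for CCRL2 at 1 h (-49.3 nt) and HNRNPU at 2 h (66.8 nt).

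For PAS usage a library left out gave 0 to 50, 0 to 42 and 0 to 44 at 1, 2 and 4 h. For mRNA beyond nascent RNA it gave 0 to 3434, 0 to 3363 and 0 to 3050, the block without 0 h replicate 1 of 3′-seq 12, 66 and 258, that without 0 h replicate 2 of PRO-seq as well 263, 154 and 194, and TMM with the block 3 at 4 h. At the preset correlation camera called 38 of 76 3′-seq list tests, 30 of 76 in PRO-seq and 20 of 76 in tails, and with the block 38, 33 and 18. With an estimated correlation it called 5 of 76 3′-seq list tests, 0 with the block, and 0 in PRO-seq and in tails either way.

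The correlation of tail with nascent change was at 1 h 0.201 by Pearson, 0.116 in first and 0.126 in second replicates, 0.157 in genes with 1 isoform and 0.409 in genes whose mRNA was called with the block and without 0 h replicate 1. At 2 h it was 0.233 in second replicates and 0.569 in such called genes, and at 4 h 0.191, 0.229 and 0.430 for first replicates, second replicates and called genes. With mRNA change it was at 2 h 0.0763 in first replicates and 0.371 in called genes, and at 4 h 0.292 by Pearson, 0.226 in first and 0.255 in second replicates, 0.365 without 0 h replicate 1 and 0.367 in called genes.

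The measurements that changed sign are these. MERTK mRNA at 2 h, +1.22, gave -0.38 in DESeq2, -0.26 with upper quartile factors, -0.33 in edgeR with TMM, -0.38 with the replicate block and no 0 h replicate 1, -0.93 without 0 h replicate 1 and 3.36 without 0 h replicate 2, so the comparison of its mRNA with its nascent RNA rests on the nascent fall. With a library left out, ACTB mRNA at 4 h ran from -1.52 (without 0 h replicate 1) to 0.38 (without 0 h replicate 2) and GAPDH mRNA from -2.07 to 1.79 without the same libraries. ACTB tails at 4 h gave 1.16 nt once library medians were subtracted, with or without the replicate block. PDGFRA nascent RNA at 1 h, -0.17, gave 0.36 in DESeq2, 0.43 with upper quartile factors, 0.50 in edgeR with TMM, 0.21 with the block as well, 0.10 on TMM-scaled CPM with or without the block, and -1.65 to 1.32 without 1 h replicate 2 or replicate 1. The TNF difference between mRNA and nascent RNA at 4 h, +0.27, gave -1.12 with TMM within each assay, with or without the block, -1.19 in limma-voom, -1.30 with the block and without 0 h replicate 1 of 3′-seq and 0 h replicate 2 of PRO-seq, and -0.85 to 1.40 without PRO-seq 4 h replicate 2 or replicate 1.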

Other observations

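All tests of explanations in this part were chosen after the results were seen. Some panel genes carry no name in the tail tables and were read from 3′-seq peaks by position. PTGS2, which encodes the prostaglandin enzyme cyclooxygenase 2, went from 43.5 and 0.530 CPM at 0 h to 1693 and 290 at 4 h, CXCL10, an interferon-induced chemokine gene, from 4.35 and 1.33 to 35.8 and 1070, and IL6, the interleukin 6 gene, from 0 and 0 to 4.52 and 5.98. In limma with the block the adjusted p at 4 h was 0.0203 for PTGS2 and 0.0393 for CXCL10, and IL6 did not pass (0.182).

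The authors' own Kolmogorov-Smirnov tests, deposited per replicate, compare the read distributions of 1 isoform between 2 times. From 0 to 4 h 4260 isoforms had an FDR under 0.05 in both replicates, of which 3155 were shorter in both, 173 longer in both and 932 moved in opposite directions. From 0 to 1 h these were 1080, 81 and 714 of 1875, and from 0 to 2 h 1662, 80 and 529 of 2271. With actinomycin D from 0 to 2 h 3148 passed in both, 129 shorter, 1128 longer and 1891 in opposite directions. Such a test measures reads within 1 library and not the spread between libraries.

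The 3′-seq library of 0 h replicate 1 stands apart. Low depth alone is excluded, since the shallowest library, 1 h replicate 1, had 5.80% of its CPM in its 10 strongest peaks. The unstimulated state is excluded, since 0 h replicate 2 had 6.24%. A few strong peaks are not the whole cause either, since without those 10 its best correlation with another library was 0.480, under the lowest of 0.607 among the other 7. Reads from sites outside annotated protein-coding genes may account for it: 35.7% of its CPM lay at protein-coding genes, against 85.9 to 86.5% elsewhere. Of its 10 strongest peaks 8 lay outside protein-coding genes, so this share is in part the same observation. Whether the correlation recovers over peaks at protein-coding genes alone was not tested.

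The PRO-seq library of 0 h replicate 2 holds LPS-induced transcripts. A library of 1 h LPS, as its treatment text says, is argued against by the 10 tested chemokine genes, a list fixed beforehand. Times were taken from the titles, which are themselves in question. These genes then stood at a median of 15.1, 23.0 and 36.2% of their 1, 2 and 4 h levels in replicate 2. Counting noise is excluded, since those genes had 575 reads against 50.4 at their shares in replicate 1. Reads mixed in from the 1 h library and cells partly activated before LPS cannot be told apart. With a single shared proportion the reads would vary as counting alone: they varied 1.25 times as much in the chemokine genes but 8.49 times in 24 genes chosen for a rise of over 16-fold in replicate 1, to which transcription in the cells themselves could add. The chemokine shares were 10.6 times those of replicate 1 (median), which either explanation gives.

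Tails at neighbouring sites of 1 gene differ with the distance between the sites. In 225 pairs within 200 nt the upstream tail exceeded the downstream one with a slope of 0.733 nt per nt of distance, which is consistent with 1 pool of reads being measured against both sites, although only 12.8% of pairs 150 to 200 nt apart differ by the distance to within 10 nt. In 53 pairs 200 to 300 nt apart the median difference was still 165 nt. In 864 pairs over 300 nt apart the median difference was -3.36 nt, so upstream tails were not generally longer there. Those pairs are other sites, so they cannot exclude longer upstream tails in close pairs. In all 443 isoforms are in a pair within 200 nt, ZFP36 among them with sites 63 nt apart and tails 59.5 nt apart. The tail values of these isoforms may carry the distance to the next site, and changes in them could reflect a change in site use.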
